A study of Schizothorax plagiostomus with 18 samples.

How the data were processed

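RNA from the gonads of Schizothorax plagiostomus, a snow trout of Himalayan rivers that breeds seasonally, was sequenced in 18 libraries. Ovaries and testes were sampled at 3 maturational stages, before, during and after spawning, with 3 libraries for each of the 6 combinations. Per the labels, total RNA was extracted with Trizol, ribosomal RNA was removed with a kit made for human, mouse and rat RNA, and libraries were made with an Illumina-compatible RNA kit. Per the labels, each library also belongs to 1 of 3 seasons, and the season number equals the replicate number in every group. The labels do not state that replicates came from separate fish, so p-values measure the spread between these samples, which may be partly technical.

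The authors deposited a table of whole-number counts per feature with a column for each library, and a map from transcripts to features as text. Per the submitters' processing notes, fastp and Salmon were used, with no versions or settings recorded there. The transcriptome, the clustering of transcripts and any rounding are not given in the sources used here. Because Salmon estimates fractional counts, the deposited counts may be rounded estimates; every one of the values was whole, and the 15 values above 1000000 all ended in 0. The table held 135031 features made from 251830 transcripts. Of these, 104382 features were single transcripts and 30649 were clusters of several transcripts, which held 55.9% of all counts. Transcripts with a common stem in their identifier fell in more than 1 feature for 31828 of 168164 stems (18.9%), so reads of one gene, of duplicated genes or of alleles may be divided between features, and the level of any single feature is uncertain in that respect. The files do not pair features with gene names. Gene lists of zebrafish symbols, for gonad cell types, steroid synthesis, oocyte and sperm genes and others, were fixed before the data were examined and could not be applied for that reason. No genome was used here.

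Total counts ranged from 14600000 to 52700000 per library. A floor of 3 counts per library was used as the limit that a count of 0 allows, for counting error only. Shares and levels are given in counts per 1000000 counts (CPM), computed here from the deposited counts and the library totals. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom between libraries of a group was 23.6, over features with at least 20 counts in the pair. All 18 libraries were therefore kept as separate samples.

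Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 (glmQLFit and glmQLFTest, robust=FALSE) in R 4.3.3, after TMM scaling and the filterByExpr low-count filter on the group, with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Stage comparisons within a gonad were fitted on the 9 libraries of that gonad, with 42501 features tested in ovaries and 51080 in testes. Comparisons of testis with ovary, and the tests of whether the stage change differed between gonads, were fitted on all 18 libraries with 6 group means, with 53536 features tested. The biological coefficient of variation was 64.3% in ovaries and 57.1% in testes. Standard errors of log2 fold changes were obtained from the F statistic. Library-level values were compared with two-sided exact permutation tests in SciPy 1.17.1. With 3 libraries against 3 the smallest p such a test can give is 0.1, so stage comparisons of library-level values cannot pass 0.05. The number of detected features was counted after every library was thinned to 14600000 counts with a fixed seed.

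The rule for the features named was fixed before the data were examined. It took features with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 10 CPM in the higher group, and every library of a group above every library of the other. In the tests of differences between gonads the separation of libraries was not required, and the highest group mean had to reach 10 CPM. The first 2 in each direction by adjusted p were named, along with the 5 features of highest mean share in each gonad. Non-overlap of 3 libraries with 3 arises by chance in 10% of features with no difference. Groups of features by gonad were defined after the data were examined, from mean levels over the same libraries with the stages pooled. The stage direction of their members can therefore be partly set by this choice and is no independent evidence. Ovary-predominant and testis-predominant features had a mean of at least 1 CPM in that gonad and at least 16 times the mean of the other gonad, and shared features had at least 1 CPM in either gonad without meeting that ratio. A co-varying set was also defined then: features with a Pearson correlation of at least 0.8 over the 18 libraries, on log2(CPM + 0.1), with the most abundant feature whose libraries of a single group differed by at least 1000-fold.

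The season labels mark a shared batch, so the season number pairs libraries across groups by label, and a fit with season as a block was among the alternatives. In the data the pairing was weak. The deviations of libraries from their group means had a mean correlation of -0.01 for libraries of one season. For libraries of different seasons it was 0.005, a value largely fixed by the first because deviations from a group mean cancel out. In 1 of 15 pairs of groups, pre-spawning with post-spawning ovaries, all 3 same-season correlations exceeded 0.1 (0.187, 0.313 and 0.136). A test of the season term itself passed the threshold for 0 features in ovaries, in testes and in all libraries together by edgeR, with 5.3%, 6.3% and 3.8% of features at an unadjusted p under 0.05, and no other tool was run on that term. The other alternatives were DESeq2 1.42.0, the size factors of DESeq2 (RLE) in place of TMM, no low-count filter, leaving out each library in turn, and another choice of libraries for the fit. Leaving out the co-varying set was added after the data were examined.

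The procedure was tested on simulated counts drawn from the means, library sizes and dispersions of the real libraries, with 200 changed features per comparison. The changed features had an average log2 CPM above 1 and were kept past the filter, so recovery at lower levels was not measured. The real gonad comparisons held many more differences, so these recovery rates need not carry over to them. For spawning against pre-spawning ovaries (40976 features), edgeR recovered 7 of 100 features changed 4-fold and 76 of 100 changed 16-fold, with 4 false calls among 87. DESeq2 on the same simulated ovaries recovered 40 and 96, with 112 false calls among 248. For spawning against pre-spawning testes (48262 features), edgeR recovered 8 and 84 with 3 false calls among 95, and DESeq2 recovered 55 and 96 with 118 false calls among 269. For testis against ovary at spawning (51655 features), edgeR recovered 12 and 75 with 1 false call among 88. For the difference between gonads in the change from pre-spawning to spawning (51852 features), edgeR recovered 1 and 43 with 0 false calls among 44. A second simulation without any filter is described with the alternatives.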

Results

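Transcript abundance was measured by RNA sequencing in ovaries and testes of the snow trout Schizothorax plagiostomus before, during and after spawning, with 3 libraries per gonad and stage. The series title names season and sex as its subjects, and the design permits comparison of the gonads at each stage, of the stages within each gonad, and of the stage change between gonads. Features are transcript clusters or single transcripts without gene names, so they are described by identifier, level and gonad. Ovary libraries held 31400000 ± 10300000 counts and testis libraries 41000000 ± 9500000 (SD, n = 9 each), with 14600000 in the smallest, post-spawning ovary 1.

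The gonad separated the libraries more than any stage did. The first principal component held 60.3% of the variance of 42252 features and parted the 9 ovaries from the 9 testes. Spearman correlations across features, which are not independent replicates, ranged from 0.471 to 0.66 between an ovary and a testis. Within a group they ranged from 0.804 to 0.96 in ovaries and from 0.806 to 0.978 in testes. The 3 post-spawning testes resembled each other closely, with each one's closest library at a correlation of at least 0.975. Post-spawning ovary 1 stood apart from post-spawning ovaries 2 and 3, with a mean correlation of 0.808 with them, against 0.96 between those libraries.

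**Figure D1:**
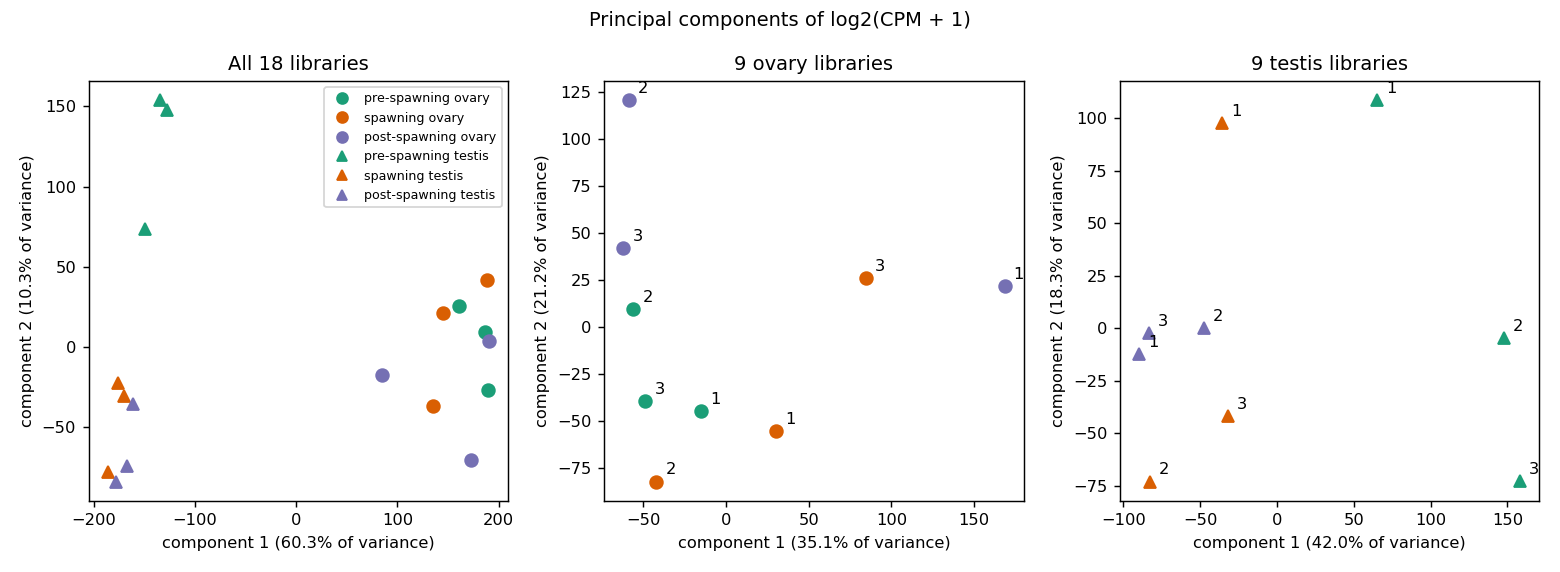
Scores of the libraries on the first 2 principal components of log2(CPM + 1), for all 18 libraries and for each gonad alone, with stage as colour, gonad as marker shape and replicate numbers printed in the single-gonad panels. The first component of all libraries (60.3% of variance) separates ovaries from testes. Post-spawning ovary 1 and pre-spawning testis 1 lie away from the other libraries of their groups. In the testis panel spawning testis 1 also lies away from its group on the second component, near pre-spawning testis 1 (97.54 and 108.6).

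Testes expressed a wider range of features than ovaries. At equal depth, 65226 ± 3273 features were detected with at least 1 count in testes and 55336 ± 1226 in ovaries (SD, n = 9 each; two-sided exact permutation test, p = 4.11e-05, Benjamini-Hochberg adjusted p = 0.000144 over 7 library-level comparisons). Every testis library exceeded every ovary library, with testes from 61987 to 73036 and the highest ovary at 57546. With at least 5 counts required the mean of ovaries minus that of testes was -4252 features instead of -9890, and the gonads overlapped, with spawning testis 2 (39882) below spawning ovary 1 (40040) and post-spawning ovary 1 (39949). With the stages pooled, counts were more concentrated in testes: the 100 most abundant features took 29.1% ± 7.07 of counts in testes and 20.2% ± 3.58 in ovaries (n = 9 each, exact permutation p = 0.00518, adjusted p = 0.00907). Pre-spawning testes, at 19.6% to 25%, lay inside the range of ovaries (15.6% to 26.9%), and post-spawning testes at 35.4% to 37.8% lay above it. For the 10 most abundant features the difference did not pass (13.5% ± 6.68 against 8.36% ± 4.29, exact permutation p = 0.0705, n = 9 each).

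The most abundant features were partly common to the gonads. The single-transcript features cluster61036 and cluster32980 were among the leading 5 in each gonad when the stages were pooled, at 1.38% ± 1.52 and 1.13% ± 1.31 of counts in ovaries and 1.49% ± 0.661 and 1.01% ± 0.542 in testes (SD, n = 9 each). Their rank in ovaries came from the spawning stage (2.73% and 2.32% on average); in pre-spawning ovaries they took 0.566% and 0.412%, below cluster55 (0.902%) and cluster70400 (0.739%). In ovaries, cluster55, made of 55 transcripts, and cluster70400, a single transcript, took 0.84% ± 0.442 and 0.696% ± 0.219, against 0.0024% ± 0.0012 and 0.0009% ± 0.0008 in testes. The large cluster cluster0, with 230 transcripts, took 3.05% ± 2.49 in testes and 0.714% ± 0.664 in ovaries. In testes cluster18, with 78 transcripts, took 3.11% ± 2.8 against 0.459% ± 0.316 in ovaries, and cluster2034, with 12 transcripts, took 1.23% ± 0.647 against 0.107% ± 0.087. The lead of cluster18 and cluster0 in testes came from post-spawning testes (6.62% and 5.94%); in pre-spawning testes they took 0.828% and 0.885%, below cluster61036 (0.899%).

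Some features were limited to a gonad within the depth of these libraries. In ovaries 111 features reached at least 1 CPM in each of the 9 libraries with at most 3 counts in any testis, and in testes 13 features met the mirrored condition. Their median level was 15.3 CPM for the ovary and 6.6 CPM for the testis features. With 0 counts required in the other gonad, 11 and 1 remained, and no test is attached to these counts. By the looser definition of predominance, 2213 features were ovary-predominant and 2038 testis-predominant. Ovary-predominant features took 14.7% to 32% of counts in ovaries, and testis-predominant features 4.19% to 10.6% in testes.

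Before spawning, 22432 of 53536 features differed between testis and ovary, 11855 higher in testis and 10577 higher in ovary (edgeR). The majority turned to ovary without pre-spawning ovary 1 (9309 against 9526), ovary 2 (7655 against 8780), ovary 3 (7418 against 8886) or testis 1 (8923 against 9875), and stayed with testis without testis 2 or 3. Of the called features 16269 differed at least 4-fold and 5997 at least 16-fold, with a median absolute log2 fold change of 2.78. The feature cluster39394 stood at 481 ± 98.1 CPM in pre-spawning testes and 6.3 ± 0.143 in ovaries (log2 fold change 5.81, SE 0.51, edgeR adjusted p = 1.15e-06, SD, n = 3 each). The feature cluster58632 stood at 17.1 ± 6.17 CPM against 0.363 ± 0.139 (log2 fold change 5.1, SE 0.43). On the ovary side cluster34590 reached 1029 ± 34.1 CPM, against 2.28 ± 0.0247 in testes (log2 fold change -9.25, SE 0.56, edgeR adjusted p = 1.24e-07). The feature cluster3334 reached 967 ± 141 CPM against 9.18 ± 2.32 (log2 fold change -7.16, SE 0.44).

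At spawning, 24298 features differed between the gonads, 12365 higher in testis and 11933 higher in ovary (edgeR, 53536 tested). A testis feature, cluster46565, had 7308 counts in the 3 spawning testes, or 52.6 ± 10.8 CPM, and 1 count in the 3 spawning ovaries. The ratio was 5270, with an exact 95% counting interval from 945 to 208000 (log2 fold change 12.12, SE 0.73). Another, cluster67467, had 4123 counts against 2, a ratio of 1490 (interval 411 to 12300, log2 fold change 10.51, SE 0.79). Such intervals pool the libraries of a group and leave out the spread between them, which the SE includes. On the ovary side cluster3334 stood at 714 ± 279 CPM against 4.53 ± 0.4 in testes (log2 fold change -7.08, SE 0.44, edgeR adjusted p = 1.28e-07, SD, n = 3 each). The feature cluster40889 stood at 34.9 ± 6.13 CPM against 0.159 ± 0.0256 (log2 fold change -7.57, SE 0.47). RLE scaling moved the median log2 fold change of all features from 0.17 to 0.33 and gave 13753 features higher in testis and 10923 higher in ovary. In the other direction, the majority turned to ovary without spawning ovary 1 (9744 against 10747), 2 (8733 against 9785) or 3 (10649 against 11052), and in a fit on the 6 spawning libraries (8870 against 9121).

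After spawning, 22207 features differed, 10395 higher in testis and 11812 higher in ovary (edgeR, 53536 tested). The testis feature cluster46565 had 5469 counts in post-spawning testes and 2 in post-spawning ovaries (log2 fold change 10.78, SE 0.69). The ratio was 1910 (exact 95% counting interval 530 to 15800, without the spread between libraries). The feature cluster59887 stood at 34.7 ± 0.768 CPM in testes and 0.348 ± 0.0607 in ovaries (log2 fold change 6.7, SE 0.5, edgeR adjusted p = 2.69e-07, SD, n = 3 each). On the ovary side cluster34590 stood at 822 ± 416 CPM against 0.773 ± 0.0871 in testes (log2 fold change -10.03, SE 0.57), and cluster64988 at 65.3 ± 11.9 CPM against 0.0649 ± 0.0382 (log2 fold change -9.79, SE 0.6). Without post-spawning ovary 1 the majority turned, with 13084 features higher in testis and 12460 higher in ovary, and DESeq2 gave 12716 and 12694. Without post-spawning ovary 2 or 3 the ovary majority widened, with 7031 higher in testis against 10080 and 6507 against 9689.

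The direction of the gonad difference was often common to the stages, which were measured in separate libraries. Features higher in testis at all 3 stages numbered 4705, and features higher in ovary at all 3 numbered 6931. For pre-spawning and spawning libraries, 7130 features were higher in testis at both, where independent lists of these lengths would share 2738, and 7989 were higher in ovary at both against 2358. For spawning and post-spawning libraries the counts were 6940 against 2401 and 8698 against 2633. All these comparisons came from a single fit with a common estimate of spread per feature. Features easily called at one stage are therefore easily called at the others, and part of the excess can come from this. A smaller group of 220 features was called in opposite directions at different stages.

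In testes, spawning libraries differed from pre-spawning libraries in 2065 of 51080 features, 937 higher and 1128 lower at spawning (edgeR). Of 1974 testis-predominant features tested, 233 rose, 55 fell and 1686 did not pass. Of shared features 588 rose and 920 fell, and of the 956 ovary-predominant features tested in testes 3 rose and 21 fell. The groups were defined by mean levels over these same testes, so features high at the later stages were favoured as testis-predominant. These directions are therefore partly set by the choice. The feature cluster27788 rose from 6.65 ± 0.521 to 55.4 ± 14.2 CPM (log2 fold change 3.66, SE 0.38, edgeR adjusted p = 0.0259, SD, n = 3 each), and cluster17726 from 2.7 ± 1.05 to 30.6 ± 9.78 CPM (log2 fold change 4.13, SE 0.43). The feature cluster1336 fell from 61.9 ± 17.5 to 3.35 ± 1.21 CPM (log2 fold change -3.56, SE 0.45), and cluster1900 from 11.8 ± 3.56 to 0.693 ± 0.0945 CPM (log2 fold change -3.49, SE 0.42). With season as a block, edgeR called 0 features (13557 at an unadjusted p under 0.05, smallest adjusted p 0.0615, that of all 4 features named). The log2 fold changes hardly moved with the block: 3.64 for cluster27788, 4.11 for cluster17726, -3.62 for cluster1336 and -3.49 for cluster1900. DESeq2 without a block called 9744. The count was 7909 without pre-spawning testis 1, 0 without pre-spawning testis 2 or 3 (10830 and 12091 at an unadjusted p under 0.05), 3440 without spawning testis 1 (2535 higher, 905 lower), 34 without spawning testis 2 (30 higher, 4 lower) and 462 without spawning testis 3 (258 higher, 204 lower), while RLE scaling gave 1169 higher and 916 lower.

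Post-spawning testes differed from pre-spawning testes in 3143 of 51080 features, 1625 higher and 1518 lower after spawning (edgeR). A fit on all 18 libraries gave 1166, against 1222 for spawning against pre-spawning, so the order of these contrasts depends on the fit. Testis-predominant features rose in 307 cases, fell in 50 and did not pass in 1617, and shared features rose in 940 and fell in 1252. As above, the groups were defined from these same libraries, which can favour rises among testis-predominant features. The feature cluster64658 rose from 1.89 ± 0.141 to 61.7 ± 8.56 CPM (log2 fold change 5.6, SE 0.45, edgeR adjusted p = 0.00545, SD, n = 3 each) and cluster62570 from 1.38 ± 0.829 to 44.2 ± 2.82 CPM (log2 fold change 5.61, SE 0.46). The feature cluster1336, which was also lower at spawning, fell to 1.78 ± 0.412 CPM (log2 fold change -4.53, SE 0.47), and cluster23554 fell from 31.2 ± 2.09 to 3.61 ± 0.682 CPM (log2 fold change -2.55, SE 0.3). The abundant clusters moved as well: cluster18 rose from 0.828% ± 0.409 to 6.62% ± 0.988 of counts (log2 fold change 3.61, SE 0.7, edgeR adjusted p = 0.0316) and cluster0 from 0.885% ± 0.663 to 5.94% ± 1.18 (log2 fold change 3.4, SE 0.74, edgeR adjusted p = 0.0383). The block on season left 1309 calls, DESeq2 gave 11221, and RLE scaling gave 2012 higher and 1234 lower. The count was 9495 without pre-spawning testis 1, 2 and 148 without pre-spawning testes 2 and 3, and 10, 14 and 8 without post-spawning testes 1, 2 and 3.

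Between spawning and post-spawning testes, 18 features passed, 9 higher and 9 lower after spawning (edgeR, 51080 tested; 8105 at an unadjusted p under 0.05). Of these, 6 were testis-predominant features that rose, while the 1974 features of that group had a median log2 fold change of -0.44, with 39% above 0, and DESeq2 called 109 of them higher and 99 lower. The feature cluster62570 rose from 1.8 ± 0.68 to 44.2 ± 2.82 CPM (log2 fold change 4.65, SE 0.44, edgeR adjusted p = 0.0163, SD, n = 3 each), and cluster11904 from 1.52 ± 0.41 to 23.8 ± 3.82 CPM (log2 fold change 3.96, SE 0.32, edgeR adjusted p = 0.00661). The feature cluster31811 fell from 39.1 ± 15.5 to 1.41 ± 0.314 CPM (log2 fold change -4.79, SE 0.46). The feature cluster38055 fell from 64.9 ± 52 CPM to 4 counts in the 3 post-spawning testes (log2 fold change -10.96, SE 1.19, edgeR adjusted p = 0.0283). The ratio was 2160, with an exact 95% counting interval from 842 to 7910 that leaves out the spread between libraries. With season as a block 3 features passed, and the edgeR adjusted p of cluster62570 and cluster31811 became 0.0523. Their log2 fold changes hardly moved with the block, at 4.63 and -4.72. DESeq2 called 2698, and RLE scaling or the removal of the co-varying set 33 each. Without spawning testis 1 the count was 177 (46 higher, 131 lower), with no low-count filter 3815 (950 higher, 2865 lower), without spawning testis 3 it was 3, and without spawning testis 2 or any of the post-spawning testes it was 0 (edgeR; 8512, 5538, 5150 and 4632 at an unadjusted p under 0.05).

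**Figure D2:**
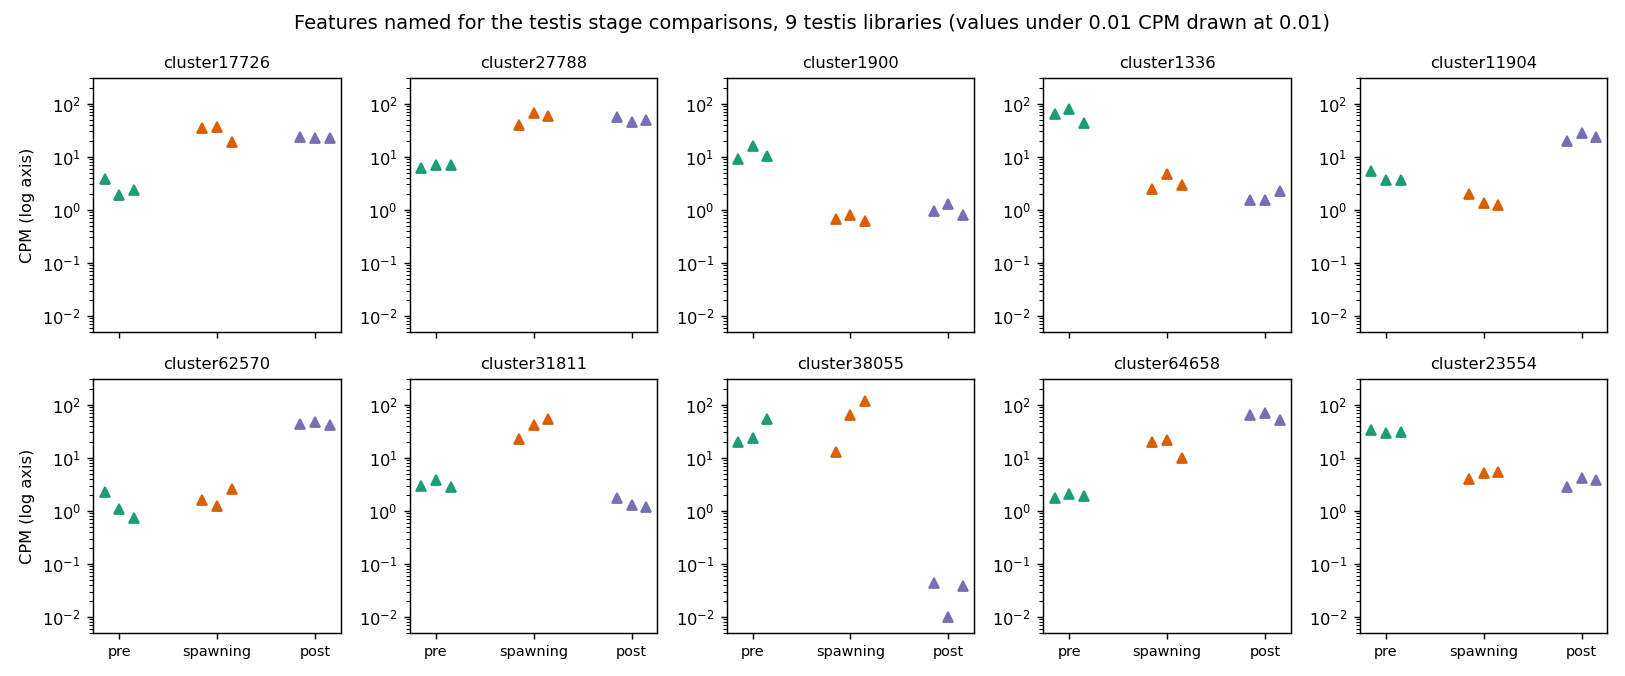
CPM on a log axis of the 10 features named for the testis stage comparisons, with a triangle for each of the 9 testis libraries, grouped by stage. Features such as cluster17726 are high in spawning and post-spawning testes (30.6 and 22.8 CPM on average) and low before spawning (2.7), whereas cluster62570 is high after spawning (44.2 CPM) and cluster31811 at spawning (39.1 CPM).

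At the level of whole libraries, testis-predominant features took 5.46% ± 1.13 of counts before spawning, 8.37% ± 2.48 at spawning and 5.15% ± 0.139 after spawning (SD, n = 3 each). Every spawning testis exceeded every post-spawning testis, the smallest exact permutation p that 3 against 3 can give (p = 0.1, adjusted p = 0.36 over 36 library-level stage comparisons). The 100 most abundant features took 21.9% ± 2.77 of counts in pre-spawning, 29% ± 6 in spawning and 36.3% ± 1.29 in post-spawning testes, where post-spawning against pre-spawning again gave the smallest exact permutation p (0.1, n = 3 each). Detected features ranged from 61987 to 66927 in testes other than pre-spawning testis 1, which had 73036.

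In ovaries, no feature passed the threshold in any stage comparison by edgeR. Spawning against pre-spawning gave 0 calls among 42501 features, with 2093 (4.9%) at an unadjusted p under 0.05, a smallest adjusted p of 0.868, and 90 calls by DESeq2. That share is about the 0.05 that no change would give. Post-spawning against spawning gave 0 by edgeR, with 3035 (7.1%) at an unadjusted p under 0.05, a smallest adjusted p of 0.0891, and 440 by DESeq2. Post-spawning against pre-spawning gave 0 by edgeR, with 3936 (9.3%), a smallest adjusted p of 0.199 and 429 by DESeq2. Ovary-predominant features had a median log2 fold change of -0.5 from pre-spawning to spawning, with 24.3% of the 2160 tested above 0, against a median of 0.01 for shared features. Ovary-predominant features were defined from these same ovaries with the stages pooled, so that direction can be partly set by the choice. Their share of counts was 28.7% ± 3.31 before spawning and 19.6% ± 4.64 at spawning (SD, n = 3 each). All 3 spawning ovaries, from 16.2% to 24.9%, lay below all 3 pre-spawning ovaries, from 25.3% to 31.9%, at the smallest exact permutation p this design allows (p = 0.1, adjusted p = 0.36). Spawning ovaries 1 and 3, at 16.2% and 17.8%, were also the ovaries with the highest share in the 10 most abundant features (14.5% and 16.4%), while spawning ovary 2, at 24.9%, had 4.64% there. After spawning the share was 24.6% ± 8.9, with 14.7% in post-spawning ovary 1 and 32% and 27.1% in ovaries 2 and 3.

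Leaving out post-spawning ovary 1 gave 41 features between post-spawning and spawning ovaries, 29 higher and 12 lower, and 25 between post-spawning and pre-spawning ovaries, 13 higher and 12 lower (edgeR, 2 libraries against 3). Of the 41, 10 were ovary-predominant, 23 shared and 7 in the co-varying set described next. The rule used elsewhere gave 7 features in this fit, a fit chosen for naming after its values were seen. The feature cluster45694 stood at 28.8 ± 12.3 CPM in spawning and 33.5 ± 10.2 CPM in pre-spawning ovaries (SD, n = 3 each). It was at 0.0431 and 0.0643 CPM in post-spawning ovaries 2 and 3 and at 13.8 CPM in post-spawning ovary 1. The feature cluster57223 stood at 0.263 ± 0.153 CPM in spawning ovaries (n = 3), at 25.8 and 19.3 CPM in post-spawning ovaries 2 and 3 and at 6.71 CPM in post-spawning ovary 1. In that library cluster33085 and cluster64191, lower after spawning, were likewise partway, at 4.66 and 6.78 CPM, against means of 0.693 and 0.677 in post-spawning ovaries 2 and 3 (n = 2). Others were at or near 0 there: cluster62618 had 0 CPM against a mean of 75.5, cluster63225 0 against 19.7, and cluster45939 0.0685 against 13.8.

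A set of 94 features (143 transcripts) varied together between libraries of the same group, at levels spanning several orders of magnitude. Its leading feature, cluster2035, ranged from 1.25 to 19365 CPM. The set took 11.8% of counts in pre-spawning testis 3, 10.8% in spawning testis 1, 6.29% in post-spawning testis 1 and 4.35% in spawning testis 2. It took 0.196% and 0.627% in the other pre-spawning testes, 0.0163% in spawning testis 3, and 0.0075% and 0.0087% in post-spawning testes 2 and 3. In ovaries it ranged from 0.0094% to 0.624%, with the highest shares in post-spawning ovaries 2 and 3. Because the set was built on a feature chosen for a range of at least 1000-fold inside a group, met in spawning and post-spawning testes, no test of it between gonads or stages that uses those groups is given. Between post-spawning and spawning ovaries 0 of 87 members tested passed by edgeR, with 86 at an unadjusted p under 0.05 and 55 calls by DESeq2, all 87 with a higher level after spawning. Before spawning, 15 of the 94 were higher in testis than in ovary by edgeR, and 79 by DESeq2. Members were chosen for their correlation with 1 feature over all 18 libraries, so their common direction follows from the choice. The numbers of members are therefore not independent evidence of a change in either comparison.

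**Figure D3:**
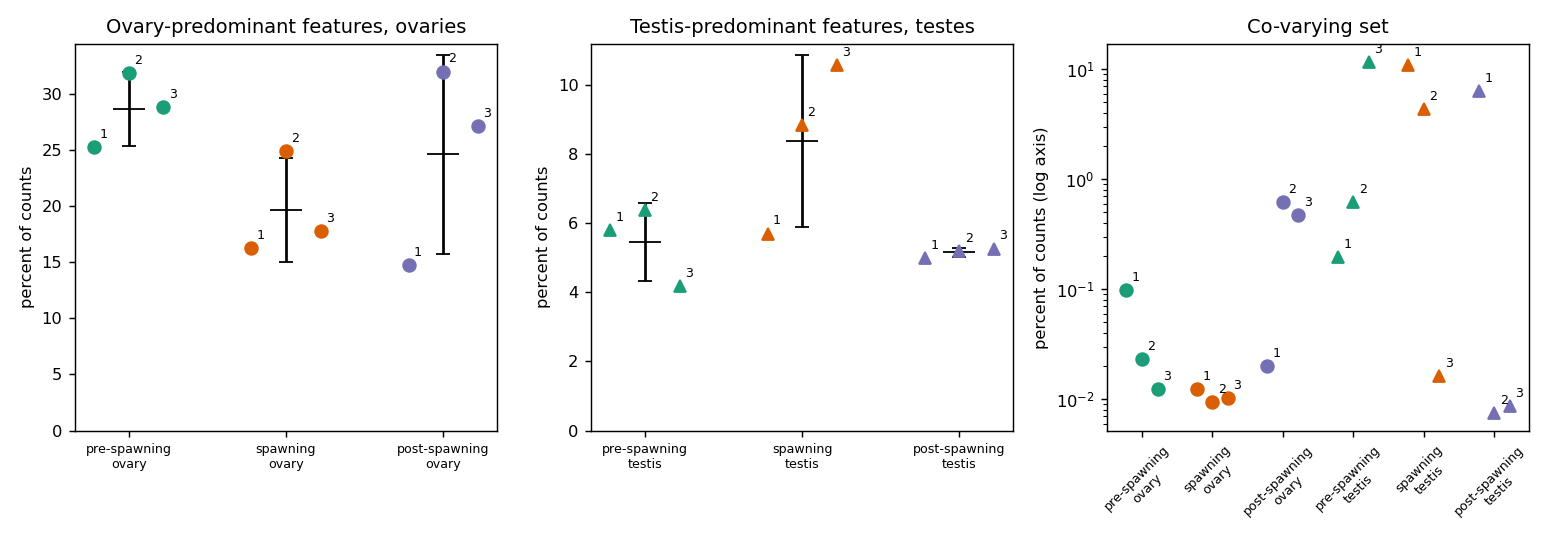
Percent of counts in ovary-predominant features for ovaries, in testis-predominant features for testes, and in the co-varying set for all libraries on a log axis, with a symbol per library, replicate numbers beside it, and bars for mean ± SD (n = 3) in the first 2 panels. Spawning ovaries lie at 16.2% to 24.9%, below the pre-spawning ovaries, and the set ranges from 0.0075% to 11.8% within the testes.

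The change between stages was compared directly between the gonads. From pre-spawning to spawning, 8 of 53536 features changed differently in testis and ovary, 6 with a higher and 2 with a lower change in testis (edgeR). The feature cluster8709 went from 17.2 ± 6.18 to 145 ± 63.7 CPM in testes and from 226 ± 56.2 to 71.9 ± 55.8 CPM in ovaries (log2 difference 5.49, SE 0.77, edgeR adjusted p = 0.027, SD, n = 3 each). The feature cluster19653 went from 2.95 ± 0.587 to 25.7 ± 13.2 CPM in testes and from 30.4 ± 8.18 to 25.4 ± 5.1 CPM in ovaries (log2 difference 4.02, SE 0.57). In the other direction cluster12404 went from 6.25 ± 0.951 to 0.721 ± 0.306 CPM in testes and from 5.01 ± 0.94 to 14.6 ± 2.75 CPM in ovaries (log2 difference -4.07, SE 0.51), and cluster24689 had a log2 difference of -4.41 (SE 0.69, edgeR adjusted p = 0.0473, or 0.0546 with RLE scaling). With season as a block 0 features passed (6799 at an unadjusted p under 0.05), and DESeq2 without a block called 1398. The count was 203 without pre-spawning testis 1, 65 without spawning testis 1, 4 without pre-spawning ovary 1 or spawning ovary 2, 1 without pre-spawning ovary 3, spawning ovary 1 or spawning testis 3, and 0 without any of the other 5 libraries (edgeR; 6072 to 8190 features at an unadjusted p under 0.05).

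From spawning to post-spawning, 5 features changed differently, 1 with a higher and 4 with a lower change in testis (edgeR, 53536 tested). The feature cluster62570, which rose in testes, stood at 0.934 ± 0.599 CPM in spawning and 0.222 ± 0.109 in post-spawning ovaries (log2 difference 6.7, SE 0.85, edgeR adjusted p = 0.00634, SD, n = 3 each). The feature cluster19653 went from 25.7 ± 13.2 to 1.12 ± 0.241 CPM in testes and from 25.4 ± 5.1 to 29 ± 7.03 CPM in ovaries (log2 difference -4.83, SE 0.58), and cluster31811 had a log2 difference of -5.37 (SE 0.67). DESeq2 called 1366 features, RLE scaling 12 and the fit without the co-varying set 9. The count was 85 without post-spawning ovary 1, 10 without spawning ovary 3, 11 without spawning testis 3, 8 without post-spawning ovary 3, spawning testis 1 or spawning testis 2, and 3 without post-spawning ovary 2, post-spawning testis 2 or post-spawning testis 3.

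Across 38829 features tested in both gonads, the stage changes of ovary and testis were weakly correlated. Spearman's coefficient was 0.095 (Pearson 0.104) for spawning against pre-spawning, -0.103 (Pearson -0.078) for post-spawning against spawning and 0.195 (Pearson 0.151) for post-spawning against pre-spawning. These coefficients are across features, which are not independent replicates, and the libraries of the gonads are separate. Without spawning ovary 3 the first coefficient became -0.053. No feature was called in both gonads, as none was called in ovaries by edgeR. There 2093 to 3936 features (4.9% to 9.3%) stood at an unadjusted p under 0.05, and DESeq2 called 90 to 440.

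**Figure D4:**
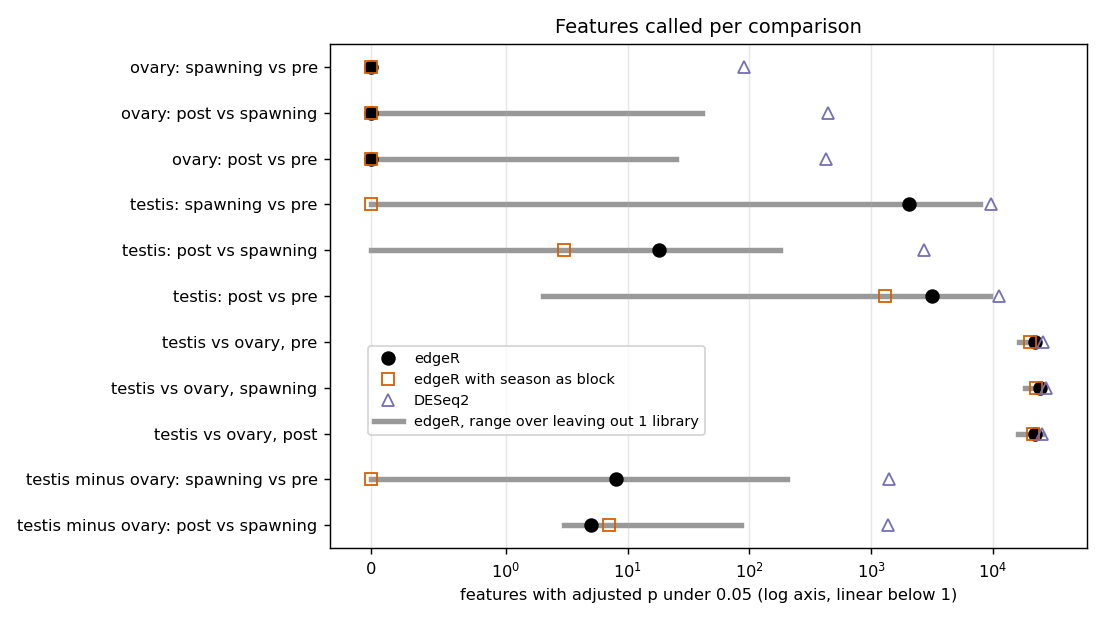
Number of features with an adjusted p under 0.05 in each comparison, on an axis that is logarithmic above 1 and linear below. Filled circles are edgeR, squares edgeR with season as a block, triangles DESeq2, and grey bars the range of edgeR over leaving out each library; the gonad comparisons lie at 22207 to 24298, while testis stage comparisons run from 0 to 9495 as libraries are left out.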

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

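The tests of testis RNA, of a wrong label, of gonad or stage and of season in this part were chosen after the results they bear on were seen; so were the splits that keep the season pairs in both gonads and the separate count of splits that regroup both gonads, while the tests of depth, of a mixture, of a common source and of the other splits were set beforehand. The values that stand apart were sought in 12 sets of 9 libraries (6 measures in each gonad), of which chance would mark about 1 in 20.

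Pre-spawning testis 1 had 73036 detected features at equal depth, far from the other 8 testes (61987 to 66927). This holds with 1 count taken as detection; with 5 counts it had 47970 against 39882 to 45560, a gap of 0.298 of the range and under the limit of 0.493. Post-spawning ovary 1 had 0.284% of its counts in testis-predominant features, far from the other 8 ovaries (highest 0.16%). The change from pre-spawning to spawning differed between testis and ovary in 8 features, and the change from spawning to post-spawning in 5, by edgeR's test of the difference itself.

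Post-spawning ovary 1 stood apart from the other ovaries: at equal depth its median Spearman correlation with them was 0.763, which was 5.11 SD below the mean of the other 8 libraries' medians (0.869), so its low total is argued against as the reason. Testis RNA in this library is argued against only if it began at the mean of the other ovaries. Diluting ovary-predominant features from that mean (25.5%) to the 14.7% seen would need 2.75% of counts in testis-predominant features. The library had 0.28%. Spawning ovaries 1 and 3 stood at 16.2% and 17.8% in ovary-predominant features, and from such a level less testis RNA would be needed. Testis RNA is therefore not excluded. Testis-predominant features were defined with this library among the ovaries, which may weaken the test. The library also lay nearest the testes on the first component of all libraries (84.56, next ovary 135.21). A wrong stage label cannot be told apart from an unusual ovary. Its mean correlation with the spawning ovaries was 0.854, above its 0.808 with the libraries of its own group but below the lowest correlation inside the spawning group (0.874) by about the SD of those correlations (0.019), and its closest library was spawning ovary 3 (0.896). A difference in how far this ovary had regressed or matured after spawning was not tested and may also account for it.

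The co-varying set of 94 features was built on a feature chosen for a range of at least 1000-fold inside a group, met in spawning and post-spawning testes, so the wide range there was fixed by the choice. Gonad or stage alone is argued against by the other 4 groups, of which 2 held libraries that differed over 10-fold in the share of the set (30.9-fold in post-spawning ovaries and 60.1-fold in pre-spawning testes). The range in ovaries rests on post-spawning ovary 1 (0.0202%), whose stage label is in doubt. Post-spawning ovaries 2 and 3 were at 0.624% and 0.478%, against 0.0094% to 0.0125% in spawning ovaries, so the pre-spawning testes carry this argument. Season alone is argued against as well: ovaries of seasons 2 and 3 differed 66.4-fold and 46.9-fold, though those of season 1 differed 7.85-fold. Testes of season 3 differed 1350-fold, a range that uses a post-spawning testis and so was partly fixed by the choice. Season held 4.4% of the variance of the log2 share (permutation p = 0.706). A common source of RNA present in varying amounts was put to a test that could have gone otherwise. Of 93 features that followed the leading feature across testes, 78.5% also followed it across ovaries, against 0.8% of 13348 other features. Joint regulation of these features within the gonads would give the same, so the test cannot tell it from a source of RNA. No source was identified, as the files do not pair features with gene names. Joint regulation, another tissue or cell type carried along in dissection, blood, and another organism all stay open and untested.

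Pre-spawning testis 1 lay between the other pre-spawning testes and the spawning testes, at 0.48 on an axis with spawning testes at 0 and pre-spawning testes 2 and 3 at 1. Each library was placed on an axis built without it, where those pre-spawning testes lay at 0.76 and 0.81 and the spawning testes at 0.05 to 0.29. At equal depth its position was also 0.48, which argues against depth as the reason. A wrong label or a swap cannot be told apart, because the position is above the spawning testes by less than their own range (limit 0.53). Its closest library was spawning testis 1, of the same season, and the reverse held as well (Spearman correlation 0.894). On the second component of the testes these libraries lay together at 108.6 and 97.54, with the next highest testis at 0.03. A mixture of both kinds of testis, or a testis partway between the stages, may account for its position on the axis. Neither explains its score on the second component, where it lay above every other testis and not between the kinds. The share of pre-spawning RNA was 0.32 by features higher before spawning and 0.22 by features higher at spawning, a difference of 0.1. Single features spread widely (quartiles 0.15 to 0.6 and -0.65 to 0.75).

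Other splits of the same libraries were tested in the same way as the real groups. For each comparison of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. In testes, 1 of 10 splits, the real one, gave as many features as spawning against pre-spawning (2065; highest other 9), post-spawning against spawning (18; highest other 0) and post-spawning against pre-spawning (3143; highest other 0). For testis against ovary it was likewise 1 of 10 before spawning (22432; highest other 0), at spawning (24298; highest other 0) and after spawning (22207; highest other 0). In ovaries the real splits gave 0 features by edgeR, so all 10 splits gave as many. The real splits had 2093, 3035 and 3936 features (4.9%, 7.1% and 9.3%) at an unadjusted p under 0.05, and 90, 440 and 429 calls by DESeq2. The highest others were 0, 228 and 11 by edgeR. The 228 features came from the split that joined post-spawning ovary 1 with spawning ovaries 1 and 3, which points to a structure among these libraries other than their stage. Of the 10 splits 4 part all 3 seasons, the real one among them. The highest others in that subset were 9 for spawning against pre-spawning testes, 11 for post-spawning against pre-spawning ovaries, and 0 for the 7 other comparisons.

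For the difference between gonads in the change from pre-spawning to spawning, 3 of 100 splits drawn gave as many features as the real one (8, highest other 400). Both other drawn splits that gave as many kept the testes in their real stages, and so kept the testis change. Of the 84 drawn splits that regrouped both gonads 0 gave as many by edgeR (highest 7). Splits that regroup the testes also break up the testis stage change. The share of drawn splits therefore cannot separate a difference between gonads from that change, and chance is not excluded. Among the 32 splits that keep 1 library of each season in every group, the real one included, 5 gave as many. Season pairs the libraries by label, and only 18 splits regroup both gonads and keep 1 library of each season in every group (highest 3), too few for a share under 0.05. With season as a block edgeR called 0 features (6799 at an unadjusted p under 0.05, smallest adjusted p 0.0629), and DESeq2 without a block called 1398. The 8 edgeR calls were thus lost with season in the fit. The season term itself passed for 0 features, so the loss does not show that season removed the difference.

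For the change from spawning to post-spawning, 13 of 100 splits drawn gave as many (5; highest other 1328), so chance is not excluded. The splits with 400 and 1328 features regrouped the ovaries alone, so their counts may come from the testis change and are not evidence about the ovaries. Of the 84 that regrouped both gonads 9 gave as many, with 480 in the highest, many times the real count, which points to a structure of the samples other than stage. The 18 that also keep the seasons gave 0 each by edgeR, the only tool run on splits (1684 to 7249 features at an unadjusted p under 0.05), and are too few for a share under 0.05.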

How the results depend on the processing

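The fit without the co-varying set was chosen after seeing the data; the other settings were planned, and camera on the fixed lists was not run because features carry no gene names. The differences between testis and ovary before, at and after spawning stayed in every setting, though not the majority of higher or lower features, with counts from 16304 to 18835, 18518 to 22134 and 16196 to 25544 with a library left out. The difference in detected features kept its direction and its call, at -4252 features (ovary minus testis) with at least 5 counts and -15689 without thinning against -9890, though the gonads overlapped with at least 5 counts, and the season term gave 0 features under both scalings by edgeR (2249 and 3207 features at an unadjusted p under 0.05 in ovaries and testes; no other tool was run on it). The stage results did not hold in this way.

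With season as a replicate block, the pairing given by the labels, edgeR called 0 features for spawning against pre-spawning testes (13557 at an unadjusted p under 0.05), 3 for post-spawning against spawning and 1309 for post-spawning against pre-spawning, and 0 for the gonad difference in the first change (6799 at an unadjusted p under 0.05). No other comparison went from some calls to none or from none to some with the block, though single features did change: counts between testis and ovary moved from 22432 to 20407, 24298 to 22747 and 22207 to 21332, and the second gonad difference from 5 to 7. It takes up residual degrees of freedom, and the season term itself passed for no feature; the cause of the losses was not tested further.

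DESeq2 called more features: 90, 440 and 429 in the ovary comparisons (spawning against pre-spawning, post-spawning against spawning, post-spawning against pre-spawning), 9744, 2698 and 11221 in the same comparisons of testes, and 1398 and 1366 for the gonad differences. In simulated ovaries and testes 112 of its 248 calls and 118 of its 269 were false, which may explain part of the excess. It also recovered more of the 100 features changed 4-fold than edgeR did (40 against 7 in ovaries, 55 against 8 in testes). The simulations held only 200 changed features, so how much of the excess was false cannot be told. With no low-count filter edgeR called 1389, 1761 and 2159 in ovaries, 8584, 3815 and 9485 in testes, and 2242 and 2583 for the gonad differences. Of the 8584, 12.3% were features the filter removes, so most of the rise is in features that pass it. With every feature simulated and no filter, 135 of 244 calls in ovaries and 128 of 251 in testes were false. With the filter 9 of 83 and 4 of 105 were false. More of the 100 features changed 4-fold were also recovered without the filter (18 against 4 in ovaries, 23 against 11 in testes). False calls may explain part of that rise, but how large a part cannot be told. A fit on all 18 libraries gave 1 feature for post-spawning against pre-spawning ovaries, and 1222 and 1166 for spawning and post-spawning against pre-spawning testes; the cause was not tested. RLE scaling gave 33 for post-spawning against spawning testes and 12 for the second gonad difference, and the fit without the co-varying set gave 33 and 9. RLE scaling also moved the share of calls that were higher from 45.4% to 56.1% for spawning and from 51.7% to 62% for post-spawning against pre-spawning testes, and from 75% to 85.7% for the first gonad difference. The fit without the co-varying set moved these shares in the same direction, to 53.6%, 58.9% and 77.8%.

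With a library left out, edgeR's counts in ovaries ranged from 0 to 0, 0 to 41 and 0 to 25. Each of these ovary fits had at least 1430 features at an unadjusted p under 0.05. That lowest number, for spawning against pre-spawning without pre-spawning ovary 2, was 3.2% of features tested, under the share of 0.05 that no change would give. In testes the counts ranged from 0 to 7909, 0 to 177 and 2 to 9495, and for the gonad differences from 0 to 203 and 3 to 85. Among these stage comparisons and gonad differences, the highest count came without post-spawning ovary 1 or pre-spawning testis 1 wherever that library enters, and the 177 without spawning testis 1. Correlations of stage changes between gonads ranged from -0.053 to 0.204, -0.141 to -0.013 and 0.101 to 0.251, the sign of the first turning without spawning ovary 3 (-0.053).

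Requiring 5 CPM left 43 ovary-limited and 3 testis-limited features, and requiring 0 counts in the other gonad left 11 and 1, by construction of the stricter limits. The gonad difference for the 10 most abundant features was -5.19 percentage points (exact permutation p = 0.0705). Of 179 values for named features in the other settings, 167 kept direction and threshold, 12 lost the threshold and 0 turned; 10 of the 12 were with season as a block. Of 228 with a library left out, 153 kept both and 75 lost the threshold. Depth limits the small features: 40% of features had under 10 counts in all libraries together.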

Other observations

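No test was added for this part, and the values in it were chosen for description after the data were seen. The feature cluster31811 stood at 3.21 ± 0.564 CPM in pre-spawning, 39.1 ± 15.5 in spawning and 1.41 ± 0.314 in post-spawning testes (SD, n = 3 each), a peak at spawning, while cluster11904 stood at 4.29 ± 1.04, 1.52 ± 0.41 and 23.8 ± 3.82 CPM. The feature cluster38055, at 32.6 ± 18.9 and 64.9 ± 52 CPM before and at spawning, had 4 counts in the 3 post-spawning testes together.

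In ovaries, the co-varying features had medians of -2.99, 6.91 and 3.76 for the log2 fold change of spawning against pre-spawning, post-spawning against spawning and post-spawning against pre-spawning, with no call by edgeR (22, 86 and 44 of 87 members at an unadjusted p under 0.05; 0, 55 and 8 calls by DESeq2). The members were chosen to vary together, so these counts are not independent of each other. The abundant single-transcript features cluster61036 and cluster32980 were highest in spawning ovaries on average, at 2.73% ± 2.03 and 2.32% ± 1.73 of counts, but ranged from 0.472% to 4.41% and from 0.366% to 3.65% within that group (SD, n = 3). Ribosomal RNA was removed with a kit made for human, mouse and rat RNA; whether these features are ribosomal was not tested.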
